A study of Mus musculus with 5 samples.

How the data were processed

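Total RNA was profiled in 5 libraries of primary nephron progenitor cells from C57BL/6J mouse embryos, 2 from Dis3l2+/+ (WT) and 3 from Dis3l2-/- (KO) embryos, collected after 1 passage. Per the labels, RNA was taken with a kit that keeps small RNA, treated with DNase on the column, made into stranded total RNA libraries and read from a single end on an Illumina HiSeq2500. Total RNA libraries made this way keep messages without a poly(A) tail, and very short RNAs can be lost during fragment selection. Whether each library came from a separate embryo or litter is not given in the sources used here, so p-values measure the spread between these libraries, part of which may be technical.

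The submitters' processing notes name HISAT2 2.1.0, featureCounts, edgeR 3.20.1 and the mouse build mm10. The version of featureCounts, the annotation release, the treatment of strand and of reads with several matches, and the form of normalization are not given in the sources used here. Reads that match several near-identical small RNA genes can therefore be split, dropped or assigned to a single copy. The deposited table holds 53927 genes. For each library the authors gave a signal, the CPM of an effective library size, rounded to 2 decimals. The product of the 5 deposited column sums, each taken per M, is 1.000, as the authors' edgeR normalization factors would give. The same table holds the authors' log2 fold change and average log2 CPM, a likelihood ratio score, and the authors' p-value and FDR, which were adjusted over all 53927 genes, including 25172 at 0 in every library. These comparison values are quoted only as the authors' deposited table and carry no error of their own here.

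Low values lie on steps of 1 read, from which the depth of each library was read. It came to 22.34 M and 28.26 M assigned reads in WT replicates 1 and 2, and 49.25 M, 32.23 M and 19.61 M in KO replicates 1, 2 and 3. In every library 100.00% of the values under 100 CPM lay within 0.0055 CPM of a whole number of reads, where chance gives between 23.4% and 51.6%. Rounding moves a value by at most 0.23 of a read in the deepest library and less in the others, so single reads can be told apart. The rule held to before a count test asks for more, that 95% of values up to 20 reads lie within 0.1 of a whole read. It was met in WT replicate 1 (95.4%) and not in the others (45.0% to 94.8%), so no count model of KO against WT was run. Rounding alone, at 0.11 to 0.23 of a read, can exceed that 0.1 in every library. As 100.00% of these values lay within 0.0055 CPM of a whole read, the misses are of the size that rounding gives. They are no sign that the values are not counts. The level of 3 reads, given as a floor, and all intervals on levels cover counting error only. KO replicate 1 is the deepest and KO replicate 3 the shallowest, so counting error is smallest in the former.

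Differences were tested with limma 3.58.1 in R 4.3.3, using its trend option on log2(CPM + 1), with genotype as the 1 term and all 5 libraries. Genes were kept with at least 0.5 CPM in at least 2 libraries, which left 14884. P-values are two-sided and were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes with low values. The planned test was a count model, with this limma fit as the stated replacement for a table of normalized values. The test, the groups, 36 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera also takes its p-value from the 3 residual degrees of freedom, so few lists could pass. The smallest unadjusted p it gave was 0.0203, so a loss there does not by itself show correlation among members. Of the lists, 35 had enough measured members, and the erythroid list, with 1 measured, was not tested. Named genes were Dis3l2, Igf2, H19, Six2 and Cited1 whatever their values. To these were added up to 10 genes in each direction past the threshold with a mean of at least 5 CPM and no overlap between genotypes, or the 5 with the smallest p where none passed. From each list up to 4 measured members with the smallest p were eligible. Other genes are named where said, after their values had been seen. Some items that these rules cover are not reported here.

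The limma steps were tested on simulated data for KO against WT, with 14821 genes, 50 of them changed at each of 4 sizes and a coefficient of variation of 12.1%. Of genes changed 2-fold 96.0% were recovered, and 100% of those changed 4-fold, 8-fold or 16-fold, with 6 false calls among 204. A simulated list of 25 genes changed 1.5-fold was called by camera, and 1.5% of 200 unchanged lists had p under 0.05. The simulated spread carries no differences between cultures beyond that coefficient, so real power was lower. Simulated genes were also drawn independently of each other. The 1.5% therefore does not give the rate of false calls for lists whose members move together.

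Replicates of a genotype were compared before use. On values rounded to whole reads, their chi-square per degree of freedom was 29.1 for the WT pair and between 60.0 and 177.7 for the KO pairs. No library was therefore a copy of another. Replicate numbers 1 and 2 occur in both genotypes, but no label says what they share, so the fit has no block and the fit with one is given only as an alternative. Positions are from GENCODE M21 on GRCm38, the assembly that mm10 names, with 53274 gene identifiers matched and 50604 of them in the same version. Coordinates are counted from 1.

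Alternatives chosen in advance were size factors by median of ratios, library totals, no filter, a stricter filter, pseudocounts of 0.1 and 5, a replicate block and leaving out each library in turn. Added after the data had been seen were a sex term, a term for the replicate 1 libraries, robust variance, removal of the trend with transcript length (lowess, span 0.2), the authors' deposited table, and a grouping of genes by annotated biotype. Lists for adipocytes, fatty acid synthesis and macrophages were also added, each written before its own test but after other values had been seen. The length correction was partial: the median log2 fold change of mRNAs of up to 1000 nt went from 0.14 to 0.08. Length sets held mRNAs with a mean of at least 5 CPM and no histones. Intervals for the median of a gene set come from order statistics, or are the full range where members are too few. These intervals treat genes as independent, although the estimated correlation between members was 0.9397 for the histone list and 0.6013 for the cholesterol list. They describe the spread over genes and not that between libraries. They replaced resampled intervals after 1 verdict, on the adipocyte list, had turned with the random draws: of 10 seeds, 4 put its lower bound below the cholesterol median and 6 above. The excess of histones over length-matched mRNAs has a resampled interval from 10000 draws. Family members of U1 and U2 were found as genes sharing at least 50% of their 12-base words. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.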

Results

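RNA was measured in primary nephron progenitor cells, the self-renewing kidney precursors that give rise to nephrons, grown from C57BL/6J mouse embryos. The cells carried either 2 intact copies of Dis3l2 (WT, 2 libraries) or none (KO, 3 libraries), and had been passaged once. Dis3l2 encodes a 3'-to-5' exoribonuclease that degrades uridylated RNA, and its loss in people causes Perlman syndrome, an overgrowth disorder with a predisposition to Wilms tumour. Total RNA was sequenced after preparation with a stranded total RNA kit. The depth read from the steps of the low values was 22.34 M and 28.26 M assigned reads in WT replicates 1 and 2, and 49.25 M, 32.23 M and 19.61 M in KO replicates 1, 2 and 3. Levels are given as CPM of the effective library size, as deposited. A gene with 3 reads has a level of 0.139 CPM in WT replicate 1, 0.105 in WT replicate 2, and 0.0639, 0.0936 and 0.141 in the KO libraries.

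The libraries also differed in sex-linked genes and in a few abundant RNAs. Xist, expressed from the inactive X chromosome, stood at 0.93 CPM in WT replicate 1 and 0.52 in KO replicate 3, against 951, 872 and 765 in WT replicate 2 and KO replicates 1 and 2. The Y-linked Ddx3y showed the opposite pattern, with 104 and 128 CPM in WT replicate 1 and KO replicate 3 and at most 0.19 elsewhere. Mitochondrial ribosomal RNA took 40.7% and 38.9% of the summed values in the WT libraries and 31.6%, 32.7% and 32.9% in the KO libraries, so every KO library lay below both WT libraries. The nuclear 7SK RNA, Rn7sk, took 3.83% and 3.51% in WT and 11.9%, 6.48% and 2.27% in KO. The first principal component, with 44.4% of the variance, ran from KO replicate 1 at -36.0 to KO replicate 3 at 24.6. The WT libraries lay between them at -3.8 and 16.3, so it did not separate the genotypes. The third component, with 16.5%, had both WT libraries above 0 (2.8 and 21.8) and all 3 KO libraries below (-1.9, -5.6 and -17.1). On it WT replicate 1 lay nearer to KO replicates 1 and 2 than to WT replicate 2. Chance alone gives such a separation on a given component in 20% of cases, and more than 1 component was looked at.

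Dis3l2 itself (ENSMUSG00000053333.15, chromosome 1, 86703808 to 87050095, plus strand, GRCm38) was examined first, because it checks the genotype labels. It stood at 16.04 and 12.2 CPM in the WT libraries and at 6.50, 4.93 and 4.70 CPM in the KO libraries. The means were 14.1 ± 2.73 (SD, n = 2) and 5.38 ± 0.98 (SD, n = 3), and every KO library lay below both WT libraries. The log2 fold change of KO over WT was -1.24 with a standard error of 0.21, which did not pass over all genes (adjusted p = 0.9545, limma with Benjamini-Hochberg adjustment). The labels do not say which part of the gene was removed, so reads from the rest of the transcript can remain. In the authors' deposited table the log2 fold change was -1.38 with an FDR of 0.00855.

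The main question of the design was which transcripts differ without Dis3l2. Among 14884 genes tested with limma and Benjamini-Hochberg adjustment, 1 gene passed, the vault RNA Vaultrc5, a small noncoding component of the vault particle. Vaultrc5 (ENSMUSG00000065145.1, chromosome 18, 36801866 to 36802008, plus strand) was at 1.99 and 1.51 CPM in WT and at 28.8, 57.0 and 46.3 CPM in KO. Its mean rose from 1.75 ± 0.34 (SD, n = 2) to 44.0 ± 14.2 CPM (SD, n = 3), and its log2 fold change was 3.98 with a standard error of 0.29 (adjusted p = 0.0471, limma). That call was lost without WT replicate 1 (adjusted p = 0.3780), WT replicate 2 (0.5129), KO replicate 2 (0.1240) or KO replicate 3 (0.0664), although the log2 fold change stayed between 3.78 and 4.26. It was also lost with median-of-ratios size factors (0.0552), no filter (0.0587), a pseudocount of 5 (0.2085), a sex term (0.7289) or the length trend removed (0.0790), the last 2 chosen after the data had been seen. Without KO replicate 1 the number of genes past the threshold was 5 and without KO replicate 3 it was 8, Vaultrc5 not among the latter. Without each of the other libraries in turn it was 0. With a replicate block, an alternative described below, limma called 390 genes, 339 higher and 51 lower, but no label says what the replicate numbers share. Without a block there were 413 genes at an unadjusted p under 0.05, 224 higher and 189 lower. With no effect at all 744 would be expected on average. Over the splits of the 5 libraries into 2 and 3 that do not follow genotype, the number ran from 46 to 2236. The gap between 413 and 744 therefore does not by itself speak for or against an effect of genotype. Every KO library lay above both WT libraries for 1168 genes and below both for 1039, together 14.8% of genes, and chance alone gives 20%. The smallest two-sided p of an exact permutation test of 2 against 3 libraries is 0.1, so single genes cannot be called by permutation.

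Other short structured RNAs stood beside Vaultrc5. The list of small structured RNAs, most of them made by RNA polymerase III or belonging to splicing and processing particles, had 14 measured members, of which 12 were higher in KO and 6 lay above both WT libraries in every KO library. Its median log2 fold change was 0.70 (camera, limma, adjusted p = 3.255e-11), which was lost with an estimated correlation (adjusted p = 0.4506 with an estimated correlation). The Y RNA Rny1 (chromosome 6, 47788069 to 47788180, minus strand) had 161 and 213 CPM in WT and 1197, 2978 and 2063 CPM in KO, a log2 fold change of 3.39 with a standard error of 0.37 (adjusted p = 0.2327 over all genes, limma). The U8 snoRNA Snord118 had 4.82 and 3.09 CPM in WT and 14.1, 15.3 and 13.8 in KO (log2 fold change 1.66, standard error 0.20, adjusted p = 0.3209, limma). Rnu1a1, a U1 small nuclear RNA, had a log2 fold change of 1.17 with a standard error of 0.27. Adjusted over the list alone, 6 members passed, against 1 over all genes. These were Vaultrc5, Rny1, Snord118, Rnu1a1, Rny3 (log2 fold change 1.07, from 789 to 1645 CPM) and Rnu2-10 (0.82), the last 2 of which were named after their values had been seen. Rnu1a1 and Rnu2-10 have near-identical copies that may share reads, so their values are uncertain. The list was not even across the KO libraries: its median over the WT mean was 1.04 in KO replicate 1, 0.88 in KO replicate 2 and 0.10 in KO replicate 3, and without KO replicate 3 the median log2 fold change was 1.05. With no filter on low values the median was 0.15 and the list still passed (camera, limma, adjusted p = 1.228e-07).

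**Figure D1:**
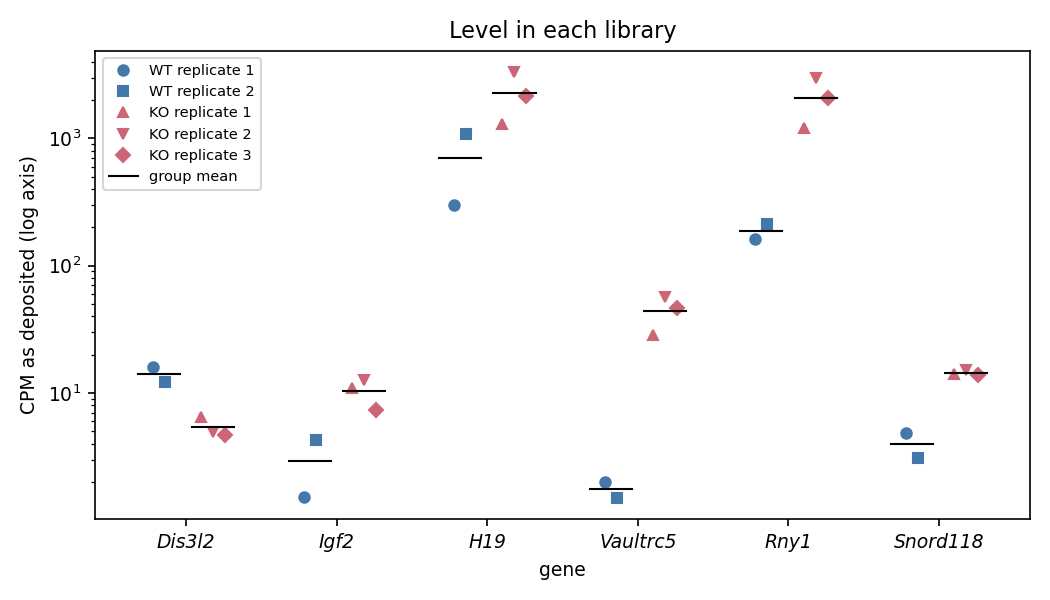
Level of 6 genes in each library, in CPM as deposited on a log axis, with 1 point per library (WT in blue, n = 2, and KO in red, n = 3) and a black line at each group mean. Dis3l2 lies lower in every KO library (4.70 to 6.50 CPM) than in either WT library (12.2 and 16.04), and the other 5 genes lie higher in every KO library than in either WT library.

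Among genes with lower levels in KO, none passed with limma, and those with the smallest p are given as values. The fatty acid receptor gene Cd36 had means of 11.7 ± 1.53 CPM in WT and 2.42 ± 1.06 in KO (SD, n = 2 and 3), a log2 fold change of -1.94 with a standard error of 0.29 (adjusted p = 0.7321, limma). St6galnac5, a sialyltransferase gene, had 11.4 ± 1.30 and 4.26 ± 0.49 CPM, with a log2 fold change of -1.24. Edil3, which encodes an extracellular matrix protein, had 28.0 ± 0.44 and 11.2 ± 2.38 CPM, with a log2 fold change of -1.26. Cavin2, a caveola gene, had 2.12 ± 0.12 and 0.67 ± 0.11 CPM, with a log2 fold change of -0.91. All 4 lay below both WT libraries in every KO library.

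The authors' deposited table, made with edgeR per the submitters' processing notes, listed 17 genes at an FDR under 0.05, of which 8 were higher and 9 lower in KO. The genes named from it in this paragraph were chosen after their values had been seen. Of the 8 higher genes, 5 were small RNA gene models: in the authors' deposited table Vaultrc5 had a log2 fold change of 4.65 (FDR = 3.58e-25), Rny1 3.48, Snord118 1.87 and the unnamed snRNA model Gm25202 2.15. The fifth, the snRNA model Gm23512, was listed at 0 in both WT libraries and averaged 0.85 CPM in KO, so no fold is given for it. The other 3 were, in the authors' deposited table, the zinc finger gene Zfp536 (3.94), the antisense transcript 2900060B14Rik (2.63) and Ltbp1, which encodes a latent TGF-beta binding protein (1.47). Zfp536 averaged 0.14 CPM in WT, close to the level of 3 reads, and 2.20 in KO. Ltbp1 averaged 22.7 CPM in WT and 63.1 in KO. The 9 lower genes in the authors' deposited table included Shox2 (-2.69), Fabp4 (-2.37), Cd36 (-2.29), Slfn5 (-1.47), St6galnac5 (-1.42), Dis3l2 (-1.38), Edil3 (-1.32) and AW551984 (-1.02). All 17 had the same sign and an unadjusted p under 0.05 with limma, and KO libraries that did not overlap the WT libraries. Both sets of values come from the same 5 libraries. 2900060B14Rik is antisense, and whether the counting used strand is not given in the sources used here, so its reads cannot be told from those of a gene on the other strand.

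The comparison also asked whether the growth factor gene Igf2 and its imprinted neighbourhood differ, because the genotype models an overgrowth syndrome. Igf2 (chromosome 7, 142650766 to 142666816, minus strand), a fetal growth factor gene expressed from the paternal copy, was at 1.53 and 4.28 CPM in WT and at 10.9, 12.8 and 7.29 CPM in KO. Its log2 fold change was 1.60 with a standard error of 0.36 and an unadjusted p of 0.0031, which did not pass over all genes (adjusted p = 1, limma). The adjacent H19 (chromosome 7, 142575529 to 142578143, minus strand), a noncoding RNA expressed from the maternal copy, was at 301 and 1089 CPM in WT and at 1285, 3314 and 2165 CPM in KO, a log2 fold change of 1.87 with a standard error of 0.59 (adjusted p = 1, limma). The WT libraries differed from each other in both genes by more than 2-fold. In the authors' deposited table Igf2 had a log2 fold change of 1.82 (FDR = 0.258) and H19 of 1.70 (FDR = 1). Igf2 overlaps the antisense gene Igf2os, which had 1.71 CPM in WT and 4.95 in KO (named after its values had been seen), so part of its reads is uncertain.

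Of the 18 measured genes of the IGF pathway list, 14 were higher in KO, 6 of them above both WT libraries in every KO library, and Igf1 lay below both (log2 fold change -0.44). The list's median log2 fold change was 0.18 (camera, limma, adjusted p = 0.0158), which was lost with an estimated correlation (adjusted p = 0.4506 with an estimated correlation) and without KO replicate 3 (0.1941). The estimated correlation was 0.0089, below the preset 0.01, so correlation among members does not account for the first of these losses. Igfbp2, an IGF-binding protein gene, had 62.1 ± 45.6 CPM in WT and 150 ± 40.1 in KO (SD, n = 2 and 3), and Igf2r, the receptor that clears Igf2, had a log2 fold change of 0.26. No member passed over all genes, and none passed adjusted over the list alone, where Igf2 had the smallest value (adjusted p = 0.0567, limma). Of 41 imprinted genes, 23 were higher, with a median of 0.13 (camera, limma, adjusted p = 0.0546). The imprinted median was -0.00 without WT replicate 2 (adjusted p = 0.2673), and the list passed without WT replicate 1 (median 0.20, adjusted p = 0.0102), KO replicate 1 (0.05, adjusted p = 0.0233) or KO replicate 2 (0.10, adjusted p = 0.0111). Cdkn1c, a cell cycle inhibitor gene in the imprinted cluster next to Igf2, had 29.8 ± 3.37 CPM in WT and 50.8 ± 7.66 in KO. In the list of Wilms tumour genes, 13 of 24 were higher and the list was not called (camera, limma, adjusted p = 0.6200). No member passed over all genes. Adjusted over the list alone (limma), the targeted gene Dis3l2 (0.0148) and Igf2 (0.0378) passed. Dis3l2 differs by design, and its smaller p eases the adjustment for Igf2. Igf2 did not pass over the IGF list (0.0567) or over the imprinted list (0.0646), so this pass is no separate support for it.

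Nephron progenitor identity was compared through 24 measured progenitor genes. Six2, the transcription factor that maintains the progenitor state, had 18.9 ± 0.11 CPM in WT and 25.7 ± 6.68 in KO (SD, n = 2 and 3), a log2 fold change of 0.39 with a standard error of 0.23 (adjusted p = 1, limma). Cited1, a marker of the least committed progenitors, varied within both genotypes, with 15.2 and 1.40 CPM in WT and 17.1, 4.74 and 2.73 in KO. Osr1 had a log2 fold change of 0.97 and Ncam1 of 0.50, each with every KO library above both WT libraries. In all, 16 of the 24 were higher, with a median of 0.11, and the list did not pass (camera, limma, adjusted p = 0.0731). Its median was -0.08 without WT replicate 2 and -0.05 without KO replicate 1, and the list passed without WT replicate 1 (median 0.39, adjusted p = 1.237e-07) or KO replicate 2 (0.18, adjusted p = 0.0047). Without KO replicate 3 its median was 0.24 and it did not pass (adjusted p = 0.1666).

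Other cell types that the cultures could hold were compared through their marker genes. Of 12 measured podocyte genes, 10 were lower, with a median of -0.24 (camera, limma, adjusted p = 0.0468), lost with an estimated correlation (adjusted p = 0.4506 with an estimated correlation), without WT replicate 2 (median -0.06, adjusted p = 0.2179) and without KO replicate 3 (0.2014). Within it Foxc2, which is also expressed outside podocytes, had a log2 fold change of 0.77. Of the 4 measured leukocyte genes 3 were lower, with a median of -0.42 (camera, limma, adjusted p = 0.0251), lost with an estimated correlation (adjusted p = 0.4506 with an estimated correlation), without WT replicate 2 (0.1012) and without KO replicate 3 (0.1724). Mrc1 averaged 3.40 CPM in WT and 1.80 in KO, and Cd68 3.01 and 2.16, while Csf1r averaged 0.94 in WT and 1.29 in KO. The 4 measured neuron and glia genes were all lower, with a median of -0.28 (camera, limma, adjusted p = 0.0468), lost with an estimated correlation (adjusted p = 0.5009 with an estimated correlation), without WT replicate 1 (median -0.13, adjusted p = 0.5905), KO replicate 2 (0.065) and KO replicate 3 (0.2911), and its median was -0.60 without WT replicate 2. Among 19 renal stroma genes, a list that did not pass (camera, limma, adjusted p = 0.5450), Aldh1a2, a retinoic acid synthesis gene, had 284 ± 56.1 CPM in WT and 149 ± 26.4 in KO, and was the 1 member to pass adjusted over the list alone. Ntn1 had a log2 fold change of 1.48 there. Of 7 measured skeletal muscle genes, 4 were lower (camera, limma, adjusted p = 0.0546), and Myl1, with a log2 fold change of -0.83, passed adjusted over the list alone. No member of these 5 lists passed over all genes, and none of the podocyte, leukocyte or neuron and glia lists adjusted over the list alone.

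The cholesterol synthesis genes formed the list with the smallest p for camera at the preset correlation and with all 5 libraries, though not with an estimated correlation or fry. Of its 20 members, 19 were lower in KO and 15 lay below both WT libraries in every KO library, with a median log2 fold change of -0.59 (camera, limma, adjusted p = 8.140e-17). Farnesyl diphosphate synthase, Fdps, had 42.9 ± 1.10 CPM in WT and 23.5 ± 5.68 in KO (SD, n = 2 and 3), a log2 fold change of -0.87. Mvd of the mevalonate pathway had 35.5 ± 6.56 and 19.2 ± 6.99 CPM (-0.90). The values for Idi1 and Dhcr7, which acts at the last step of the pathway, were -0.72 and -0.64. The call was lost with an estimated correlation (adjusted p = 0.4506 with an estimated correlation). Although 13 members had an unadjusted p under 0.05, none passed over all genes or adjusted over the list alone, where the smallest adjusted p was 0.0564 (limma). The median over the WT mean was -1.01 in KO replicate 1, -0.37 in KO replicate 2 and -0.42 in KO replicate 3, and without KO replicate 1 the median log2 fold change was -0.38.

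Replication-dependent histone genes, whose messages lack a poly(A) tail and accumulate in S phase, had higher means in KO for all 24 measured members, with a median of 0.57 (camera, limma, adjusted p = 3.192e-09, and adjusted p = 0.6908 with an estimated correlation). The KO libraries did not move together. The list's median over the WT mean was 1.20 in KO replicate 1 and 0.87 in KO replicate 2 but -0.30 in KO replicate 3, and 1 member, Hist1h4i, lay above both WT libraries in every KO library. Hist2h4 averaged 11.3 CPM in WT and 45.6 ± 32.7 in KO (SD, n = 3). No member passed over all genes or adjusted over the list alone. Without KO replicate 3 the median was 0.96, and without KO replicate 1 or WT replicate 2 it was 0.36 or 0.38. Short mRNAs moved with the histones: the 291 other mRNAs of up to 1000 nt had medians of 0.29, 0.24 and -0.13 in KO replicates 1, 2 and 3. Of 25 DNA replication genes, 19 were higher, with a median of 0.10 (camera, limma, adjusted p = 0.0251, and adjusted p = 0.5009 with an estimated correlation). Fen1 had a log2 fold change of 0.39 and Ccne1 of 0.26, and no member passed over all genes or adjusted over the list alone. The DNA replication call was lost without WT replicate 1 (0.0643), WT replicate 2 (0.1012), KO replicate 1 (0.0868) or KO replicate 3 (0.2086).

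**Figure D2:**
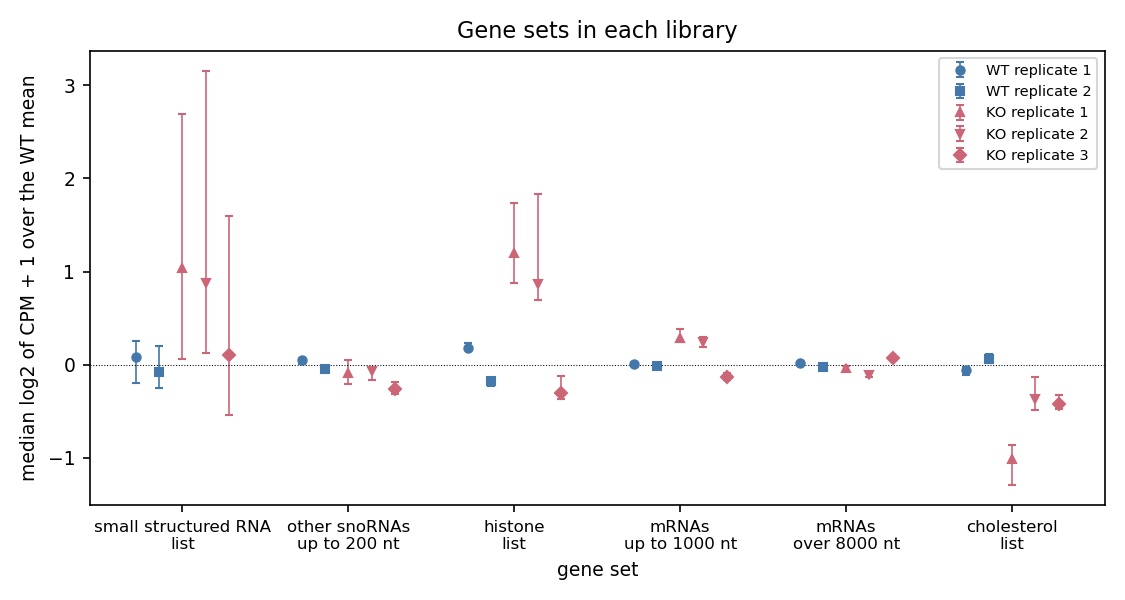
Median log2 of CPM + 1 over the WT mean for 6 gene sets, with 1 point per library (WT in blue, n = 2, and KO in red, n = 3). Bars give the order-statistic interval of at least 95% for the median over genes taken as independent, and leave out the spread between libraries. The histone list lies at 1.20 and 0.87 in KO replicates 1 and 2 and at -0.30 in KO replicate 3, and the cholesterol list lies below 0 in all 3 KO libraries.

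Genes that respond to BMP and SMAD signalling were higher in KO for 14 of 15 measured members, 6 of them above both WT libraries in every KO library. The median log2 fold change was 0.29 (camera, limma, adjusted p = 1.901e-04), lost with an estimated correlation (adjusted p = 0.4506 with an estimated correlation), and it was 0.45 without WT replicate 2. Msx2 had a log2 fold change of 0.70, and the inhibitor-of-differentiation genes Id1, Id3 and Id4 had 0.58, 0.59 and 0.48. Id3 was at 78.28 and 68.28 CPM in WT and at 129.97, 133.2 and 78.34 in KO, and Id1 at 17.16 and 18.4 in WT and at 33.44, 30.38 and 19.47 in KO, so that KO replicate 3 lay close to the WT level in both. Msx2 and Id4 had their highest level in KO replicate 3, at 4.84 and 5.36 CPM. None passed over all genes or adjusted over the list alone.

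**Figure D3:**
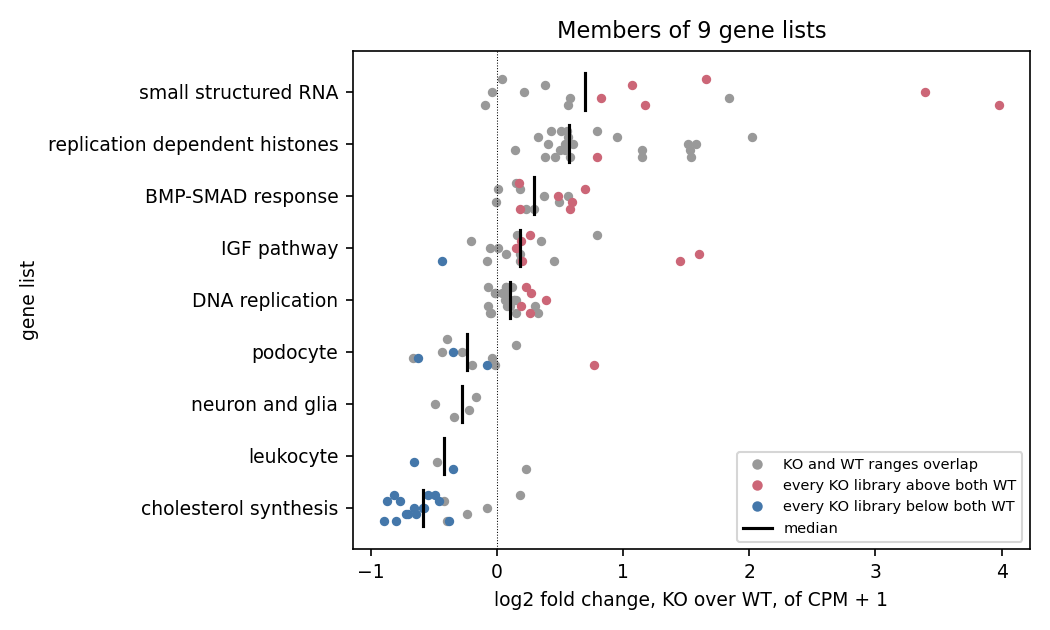
Log2 fold change of KO over WT, on CPM + 1, for each measured member of the 9 gene lists past an adjusted p of 0.05 with camera and a preset correlation, with 1 point per gene and a black line at each median. Red and blue points are genes whose 3 KO libraries all lie above or all lie below both WT libraries, and grey points are genes whose ranges overlap. The small structured RNA list has its median at 0.70 with Vaultrc5 at 3.98 and Rny1 at 3.39, and the cholesterol list has its median at -0.59.

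Of 36 lists, 35 could be tested and these 9 passed with the preset correlation. No list passed with an estimated correlation or with fry, which asks whether a list's genes move one way on balance (smallest adjusted p = 0.3302). The estimated correlation was -0.0618 for the podocyte list, -0.0651 for the leukocyte list and 0.0089 for the IGF list, all below the preset 0.01. Correlation among members therefore did not end those calls. The remaining tested lists had adjusted p between 0.0546 and 0.8447 with camera in limma. Among them were let-7 targets (median 0.05), RNA decay and uridylation genes (0.01), PI3K-AKT-mTOR and FOXO genes (-0.00), early nephron differentiation genes (0.03), ER stress genes (0.10), mitosis genes (0.10) and p53 targets (-0.02). In the RNA decay list Dis3l2, the targeted gene, was the 1 member to pass adjusted over the list alone, and none passed over all genes.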

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

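The sex term, the replicate 1 term, robust variance, removal of the length trend and the authors' deposited table were chosen after the data had been seen. The planned count models (a Wald test with DESeq2, an exact test and limma-voom) were not run, because the values are normalized and the rule for whole reads was not met, and the stricter filter used values in place of counts. Leaving out 1 of the 2 WT libraries assumes that the other varies as the KO libraries do. Dis3l2 and Igf2 kept their direction under every alternative run, with log2 fold changes of -1.43 to -0.88 and 0.96 to 2.13. Vaultrc5 kept its direction too, between 2.82 and 4.53 with limma (adjusted p from 0.0013 to 0.7289) and at 4.65 in the authors' deposited table.

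The number of genes past the threshold, 1 with limma and Benjamini-Hochberg adjustment (413 at an unadjusted p under 0.05), was 0 with median-of-ratios size factors, no filter, a pseudocount of 5, the sex term or the length trend removed (411, 1098, 413, 356 and 434 unadjusted). With the replicate 1 libraries set apart it was 3 (2 higher, 1 lower, 3 over 2-fold) and the authors' deposited table gave 17 (8 higher, 9 lower, 17 over 2-fold). Leaving out each library gave 0 to 8, all of them higher and over 2-fold, and 0 lower. Dis3l2 had -1.43 to -1.06 and Igf2 1.07 to 2.13 without each library; in the authors' deposited table Dis3l2 had -1.38 and passed. The cause was not tested.

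With a replicate block, limma called 390 genes (339 higher, 51 lower, 127 over 2-fold), Dis3l2 (-1.17, adjusted p = 0.0278) and Igf2 (1.81, adjusted p = 0.0300) among them. KO replicate 3 has no partner and adds nothing to that estimate, so the medians and fold changes equal those without KO replicate 3, and the fit without that library and without a block called 8 genes. The numbers pair 2 libraries with 2, no label says what they share, and 1 residual degree of freedom is left. Across genes, which are not independent replicates, deviations from the group mean correlated at 0.41 for replicate 1 and 0.54 for replicate 2. The deviations of the 2 WT libraries are mirror images of each other. Pairs of unlike number therefore gave -0.41 (WT replicate 2 with KO replicate 1) and -0.54 (WT replicate 1 with KO replicate 2). Both values rest on the same WT difference and are not independent evidence of a pairing.

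Lists past the threshold, 9 with camera, numbered 16 with the sex term, 15 with replicate 1 set apart, 15 with the length trend removed, 4 to 17 without each library (4 without KO replicate 3), and 0 with an estimated correlation or fry. Under both of those every call was lost at its own median: small structured RNA 0.70, histones 0.57, BMP-SMAD 0.29, IGF 0.18, DNA replication 0.10, cholesterol -0.59, leukocyte -0.42, neuron and glia -0.28 and podocyte -0.24. The replicate block, which also sets KO replicate 3 aside, ended the calls of IGF (0.16), DNA replication (0.10), podocyte (-0.31), leukocyte (-0.31) and neuron and glia (-0.27). With it small structured RNA had 1.05 and histones 0.96, as without KO replicate 3, both still called. Still called, too, were small structured RNA with no filter (0.15), leukocyte with no filter (-0.11) and pseudocounts of 0.1 (-0.65) and 5 (-0.17), and BMP-SMAD (0.18) and neuron and glia (-0.18) with a pseudocount of 5. Podocyte lost its call with median-of-ratios factors (-0.26), no filter (-0.13) and the length trend removed (-0.24), and neuron and glia with the first 2 (-0.30 and -0.07). Medians without each library ran from -0.31 to -0.06 for podocyte, -0.56 to -0.31 for leukocyte, -0.60 to -0.13 for neuron and glia, 0.12 to 0.23 for IGF and 0.07 to 0.11 for DNA replication. The cause was not tested.

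Reversed values were those of Cited1, at -1.15 without WT replicate 2, -0.43 without KO replicate 1 and -0.02 in the authors' deposited table (-1.15 to 1.60 without each library), and of the nephron progenitor list, at -0.08 without WT replicate 2 and -0.05 without KO replicate 1 (-0.08 to 0.39 without each library). The imprinted list had -0.00 without WT replicate 2 and 0.06 with no filter, against 0.13. These 2 lists, not called with all libraries, passed under 8 alternatives each. The cause was not tested.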

Other observations

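Every test in this part was chosen after related values had been seen. Intervals in this part treat the genes of a set as independent and leave out the spread between libraries. Grouped by annotated biotype, small nuclear RNAs and small nucleolar RNAs had medians of opposite sign, a difference that was not itself tested. Also past the threshold were misc_RNA models, 16 of 22 higher (median 0.20, camera, limma, adjusted p = 0.0026). Sense-intronic models had 68 of 99 lower (-0.06, camera, adjusted p = 0.0102) and TEC models 449 of 785 lower (-0.02, camera, adjusted p = 0.0327). None of these classes passed with an estimated correlation. Of 44 measured snRNA models 34 were higher in KO, 19 above and 7 below both WT libraries in every KO library, where chance gives 10% each way. Their median log2 fold change was 0.21 (camera, limma, adjusted p = 6.122e-06, and adjusted p = 0.4345 with an estimated correlation). Of 89 snoRNAs 69 were lower, 19 of them below both WT libraries, with a median of -0.13 (camera, limma, adjusted p = 1.766e-06, and adjusted p = 0.4345 with an estimated correlation). Snord118, at 1.66, stood against that direction. The 12 scaRNAs, which guide modification of snRNAs, had a median of -0.14 (camera, limma, adjusted p = 0.0255, and adjusted p = 0.6257 with an estimated correlation). Many snRNA models are near-identical copies, so these counts are not of independent genes. Copies of U1 and U2 made up 21 of the 44 and 12 of the 19 above, and their summed values had KO to WT ratios of 0.92 (U1) and 1.00 (U2). The other 23 models had a median of 0.18 and a ratio of summed values of 1.01, so a rise of snRNA as a whole was not shown.

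Genes of fat cells and fatty acid synthesis were compared because Cd36 and Fabp4 were low in KO. The adipocyte list left out Cd36, Fabp4, Plin1, Lpl and Cavin2, whose values had been seen. In the authors' deposited table these had log2 fold changes of -2.29, -2.37, -1.95, -1.95 and -1.68. Of 15 measured adipocyte genes, from 22 listed without them, 10 were lower, with a median of -0.18 (camera, limma, adjusted p = 0.0024, and adjusted p = 0.1401 with an estimated correlation). Lpin1, the most abundant of them, averaged 53.6 CPM in WT and 38.6 in KO, Adipoq 1.09 CPM in WT and 0.26 in KO, and Pparg 3.87 and 1.71, while Car3 went from 0.99 CPM to 2.61, above both WT libraries in every KO library. Of 12 fatty acid synthesis genes 9 were lower, with a median of -0.22 (camera, limma, adjusted p = 0.0015, and adjusted p = 0.1401 with an estimated correlation). Scd2, the most abundant of these, averaged 3060 CPM in WT and 2637 in KO, and its ranges overlapped.

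The higher level of the small structured RNA list in KO may have more than 1 source. A rise of every short RNA in KO was not seen. The snoRNAs of up to 200 nt outside the list had a median of -0.12 (interval -0.20 to -0.10), against 0.70 (0.04 to 1.84) for the list. These snoRNAs stood at -0.09, -0.07 and -0.26 in KO replicates 1, 2 and 3. Better recovery of short RNAs cannot be excluded by them, because a lower output of these snoRNAs in KO would hide it. A difference of KO replicates 1 and 2 from the other libraries had the values it needs for the list as a whole, whose median in KO replicate 3 was 0.10 (-0.54 to 1.60), while Vaultrc5, Rny1 and Snord118 were higher in all 3 KO libraries. Sharing of reads among near-identical copies cannot be told apart from a change of Rnu1a1 and Rnu2-10: the summed U2 values had a KO to WT ratio of 1.00 and the U1 values of 0.92. A direct effect of losing the nuclease stays a hypothesis that these libraries leave open.

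Histone messages were higher in KO replicates 1 and 2 and not in KO replicate 3. For better retention of short transcripts, the histone list exceeded length-matched mRNAs by 0.68 (0.51 to 1.36) in KO replicate 2 and by 0.96 (0.67 to 1.45) in KO replicate 1. Length was that of the longest annotated transcript, with a median of 742 nt for the histones and 834 nt for the matched mRNAs. The mRNAs of up to 500 nt had medians of 0.92 (0.13 to 1.41), 0.21 (-0.01 to 0.83) and -0.45 in KO replicates 1, 2 and 3. In KO replicates 1 and 2 these intervals overlap those of the histones (0.88 to 1.74 and 0.70 to 1.83). The match therefore cannot exclude length as the whole cause. More cells in S phase was not settled. The DNA replication list had a median of 0.11 (0.05 to 0.17) in KO replicate 3. It had 0.14 (-0.00 to 0.33) and 0.07 (-0.00 to 0.16) in KO replicates 1 and 2, and the intervals overlap. A rise of that list as large as the histones' 1.20 and 0.87 is argued against in those 2 libraries, and a smaller one stays open. Genotype alone does not part KO replicate 3 from its group, and no biological explanation of that difference was tested.

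The lower cholesterol synthesis genes in KO were set against 3 technical or cell-mixture explanations. A transcript length trend is argued against by length-matched mRNAs, with a median of 0.03 (-0.02 to 0.09) against -0.72 to -0.42 for the list. Fewer adipocyte-like cells could not be excluded, because the adipocyte list, without the genes already seen, had a median of -0.18. Its interval of -0.71 to 0.04 reaches the cholesterol median of -0.59. For fewer macrophages, 4 of 14 listed genes were measured, 3 of them also in the leukocyte list, with a median of -0.33. Their full range of -0.48 to 0.23 does not reach -0.59, though it overlaps the cholesterol interval. In WT they averaged 0.94 (Csf1r) to 3.01 CPM (Cd68), against 24.6 (Idi1) to 43.9 (Dhcr7) for the cholesterol genes named above. At such low levels the added 1 CPM shrinks a change, and Mrc1 of the leukocyte list had -0.66. The share of macrophages was not measured. A fall of these markers as large as the cholesterol median was therefore not seen, and a part played by macrophages could not be excluded. An effect of genotype on the pathway stays open beside these.

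The splits of the 5 libraries into 2 and 3 number 10. The genotype split gave 1 gene past the threshold with limma, and the highest other split, KO replicates 1 and 2 against the rest, gave 71, which points to a structure of the samples beside genotype. The pair of replicate 1 libraries against the rest gave 38 and the pair of replicate 2 libraries 13. The libraries with Y-linked expression, WT replicate 1 and KO replicate 3, gave 5. With 10 splits no share under 0.05 can be had.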
